A study of Homo sapiens with 12 samples.

How the data were processed

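RNA from 12 samples of human prostate cancer cells was measured on Illumina BeadChip expression arrays, with 1 array per sample and 3 arrays in each of 4 groups. Per the labels, the cells were transfected with 25 nM of a Stealth siRNA against GATA2 (siGATA2; 1 siRNA is named) or with a non-targeting control (siNT), and RNA was taken after 72 h. The average RNA integrity score was 9.9, and RNA was amplified and labelled with biotin using the Illumina TotalPrep kit.

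The deposited non-normalized table holds, for 47323 probes, the probe intensity on a linear scale without background correction or normalization. Beside each intensity, the deposited table gives a detection p-value per probe and array. It moves in steps of 1 in 770 negative controls. The authors also gave processed log2 values for 23043 probes. The labels name lumi for these; its version, its settings and the transform are not given in the sources used here. The processed log2 values have a median of 8.02 on each array, and on each array they correlate with log2 of the non-normalized intensity at r = 0.995 to 0.998 across probes. They were used as an alternative source.

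Intensities were processed with limma 3.58.1 in R 4.3.3. Background was corrected and arrays were quantile normalized with neqc (offset 16), taking the level of the negative controls from the detection p-values. Probes with a detection p under 0.05 on at least 3 arrays were kept (22539 probes). Symbols came from a probe table that lists 16978 probes; 16973 of these have 1 symbol and 5 have several. The 6672 kept probes without a single symbol were left out of the gene counts, and their calls are given apart. For each symbol the kept probe with the highest mean log2 intensity over the arrays was used, which gave 11933 genes, 3161 of them with more than 1 kept probe. Genes with probes called in both directions numbered 15 for Abl, 5 for MDVR, 1 for the difference and 58 for the siNT groups, and none of these is among the genes that the naming rule below picks.

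A linear model of the 4 group means was fitted to the 12 arrays (8 residual degrees of freedom), with variances moderated by eBayes with a trend (10.4 prior degrees of freedom). The contrasts were siGATA2 minus siNT in Abl, the same in MDVR, the MDVR effect minus the Abl effect, and MDVR minus Abl under siNT. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. No replicate block was used in the reported fit. The labels do not say whether the replicates of a group were separate cultures, so the p-values measure only the spread between these samples. The number of arrays limits the precision, and the median standard error of a log2 fold change was 0.13 within a line and 0.19 for the difference between lines.

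Counts of genes called in both lines were set against the count expected from independent calls. In addition, 30 gene lists on hormone response, the cell cycle, metabolism, stress and cell type were tested with camera (preset correlation 0.01), and the p-values of the 120 tests were adjusted together. The same tests were run with an estimated correlation and with fry. Fry asks whether the genes of a list move, on balance, one way, and does not compare a list with other genes. The comparisons, the lists, the naming rule and the alternatives were set before the data were examined, apart from 1 alternative and the tests named as later ones. The rule names GATA2 and the fixed genes FOXA1, HOXB13, KLK3, TMPRSS2, FKBP5, MYC and FOXM1. It adds the 10 largest rises and 10 largest falls among called genes whose arrays do not overlap between the groups (5 and 5, with no condition on overlap, for the difference), and up to 4 members of each list described, those with the smallest adjusted p. Members outside it, which are named because a count was small, were chosen after their values were seen. Other fixed genes of the rule are not reported here. Where a probe was detected on no array of a group, the change is given as a lower bound. The bound takes, for each array of that group, the lowest log2 intensity of any detected probe on the array, or the probe's own value if higher. These bounds hold for the reported background correction only, and log2 changes are smaller on values with less correction.

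Each alternative was run on its own against the reported fit, and some, such as the authors' values, replaced several settings together. They covered no background correction, normexp with offset 50, median scaling, cyclic loess, the authors' values, 2 other detection filters, other ways to combine probes, other estimates of spread, array weights, replicate blocks, a minimum fold of 1.5 and leaving out each array. A replicate block within each line rests the change within a line on replicates 2 and 3 alone, the numbers present under both siRNAs. Replicate blocks also leave fewer residual degrees of freedom, so a call can end through lost precision. The fit was also tested on simulated data with the levels and spreads of the measured genes, in which 50 genes per fold size were changed in Abl. It recovered 6% of the changes of 1.25-fold, 48% of those of 1.5-fold, 80% of those of 2-fold and 100% of those of 4-fold. It made 5 false calls in the line that was altered and 0 in the other. Far fewer genes were changed there than were called in Abl (3725), which makes the adjusted threshold stricter. The simulated noise was also independent between genes, so these shares do not give the power of the reported fit.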

Results

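Gene expression was compared in 2 lines derived from LNCaP prostate cancer cells, each transfected with siGATA2 or siNT. GATA2 is a transcription factor that opens chromatin for the androgen receptor in prostate cells, and the comparison asks which RNAs change when it is targeted. LNCaP-abl cells (Abl) were kept in 10% charcoal-stripped serum, which is low in androgens. The enzalutamide-resistant line (MDVR) was kept in 10% fetal bovine serum, selected in 25 microM enzalutamide, an androgen receptor antagonist, and maintained in 10 microM. Serum and enzalutamide therefore differed together with the line. Each of the 4 groups had 3 arrays, with 19103 to 20513 probes detected per array (40.4% to 43.3%) and a median raw intensity of 126 to 143. Log2 intensities of arrays from 1 group correlated at r = 0.989 to 0.992 across probes, those of siNT against siGATA2 arrays at 0.977 to 0.981 in Abl and 0.983 to 0.986 in MDVR, and those of Abl against MDVR arrays at 0.928 to 0.946.

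The siRNA target itself was read by probe ILMN_2102670, detected on all 12 arrays. In Abl its normalized log2 intensity was 9.11, 8.80 and 8.82 under siNT and 8.43, 8.58 and 8.48 under siGATA2. GATA2 fell by 0.41 on the log2 scale (SE 0.12, 1.33-fold, adjusted p = 0.0101), which leaves 75.04% of the siNT level. Without Abl siNT replicate 1 the change was -0.31 and no longer passed (adjusted p = 0.0576). Nor did it pass with a replicate block within each line (-0.31, adjusted p = 0.0880), which also takes that array out of the estimate. A test for a change beyond 1.5-fold could not call it (adjusted p = 1), since the estimate itself is smaller. In MDVR the probe read 8.88, 9.16 and 9.26 under siNT and 9.09, 8.80 and 8.86 under siGATA2, and these values overlap. The change was -0.18 (SE 0.12, adjusted p = 0.297, 95% interval -0.42 to 0.06), which corresponds to 88.2% of the siNT level. The GATA2 change did not differ detectably between the lines (difference 0.23, 95% interval -0.11 to 0.58, adjusted p = 0.458).

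**Figure D1:**
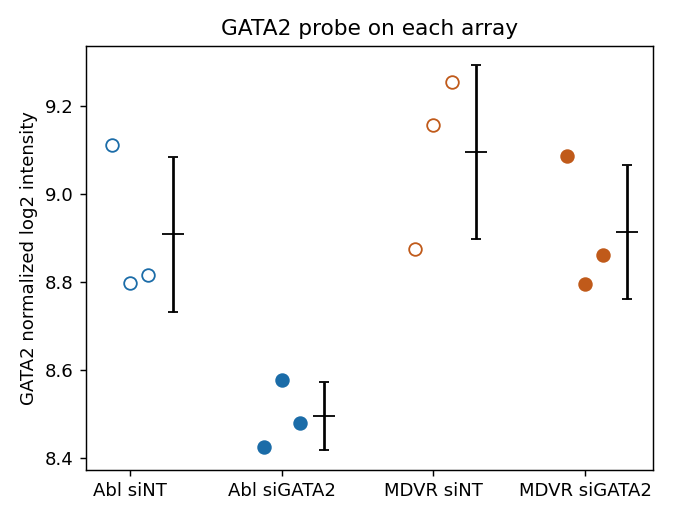
Normalized log2 intensity of the GATA2 probe on each array (points; open, siNT; filled, siGATA2) with the mean and SD of each group of 3 arrays. The siGATA2 points lie below the siNT points in Abl (mean 8.49 against 8.91) and overlap with them in MDVR (8.91 against 9.10).

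In Abl, siGATA2 lowered genes of cell division as a group, and the largest rise was that of ID1. Of 61 measured G2/M and mitosis genes, 56 fell, 1 rose and 4 were not called, with a median log2 change of -1.61 (-0.98 with no background correction and -0.74 on the authors' values). Of 45 S phase and DNA replication genes, 36 fell and 9 were not called (median -0.96). ID1, ID3 and ID2, inhibitors of basic helix-loop-helix transcription factors, rose by 4.33 (SE 0.19), 3.19 (SE 0.14) and 2.45 (SE 0.15) log2 units. MYC, a driver of cell growth, fell by 0.86 (SE 0.08), and FOXM1, a transcription factor of mitotic genes, fell by 2.04 (SE 0.14). In total 3725 of 11933 genes changed (limma, adjusted p under 0.05), 1805 higher and 1920 lower, with 184 higher and 242 lower by at least 2-fold. For 3573 of them the 3 arrays of each group did not overlap. Among all genes tested 43.2% were separated in this way, against 10% by chance. A test for a change beyond 1.5-fold called 364 genes.

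Among the G2/M genes in Abl, CDC20, an activator of the anaphase-promoting complex, fell by 2.00 (adjusted p = 2.1e-12), and TOP2A, the topoisomerase of dividing cells, fell by 2.28 (adjusted p = 1.6e-11). PTTG1, or securin, fell by 2.17, and the mitotic kinase NEK2 fell by 2.15, and AURKB, another, fell by 2.35. CEP55, DEPDC1 and CDCA3 fell by 2.26, 2.25 and 2.20. The probe assigned to PTTG3P fell by 2.28, and since this gene is a near copy of PTTG1 the source of its signal is uncertain. TUBB4B, a tubulin, was the member that rose (0.50). The list had an adjusted p = 4.7e-47 in the camera test, and adjusted p = 0.0095 with an estimated correlation. Adjusted over the list alone, 58 members fell and 2 rose. In the S phase list CDC45 (-2.15), GINS2 (-1.89), RAD51AP1 (-1.65) and FEN1 (-1.33) fell, and MCM10, a replication initiation factor, fell by 2.39 (SE 0.17). That list had an adjusted p = 1.4e-23, adjusted p = 0.0095 with an estimated correlation, and 38 members lower when adjusted over the list alone. MYC and its ribosome biogenesis targets also fell as a group, with 23 of 34 lower, 11 not called and a median of -0.36 (adjusted p = 5.3e-09; adjusted p = 0.0095 with an estimated correlation). Its members LYAR, RRS1 and FBL fell by 1.66, 0.72 and 0.62, and adjusted over the list alone 24 fell.

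Other large rises in Abl were VWF, the clotting factor carrier of endothelial cells (3.83, SE 0.18), CRYAB, a small heat shock protein (3.20, SE 0.12), and AOC1, a diamine oxidase (3.14, SE 0.16). S100P, a calcium-binding protein, rose by 2.92 (SE 0.17), CCN3 by 2.57 (SE 0.20), AKR1C3, an androgen-producing reductase, by 2.36 (SE 0.14) and RAB18 by 2.22 (SE 0.11). SPINT2, a serine protease inhibitor, fell by 2.44 (SE 0.07). Over the alternatives the smallest rises were 1.52 for VWF, 1.62 for CRYAB, 1.20 for AOC1 and 1.32 for S100P. They were 0.92 for CCN3, 0.78 for AKR1C3 and 1.10 for RAB18, and the smallest change of SPINT2 was -2.29. BRDT, a bromodomain protein of germ cells, and ODAM were detected on the 3 siNT arrays and on none after siGATA2, so they were at least 3.79-fold and 3.31-fold lower with the reported background correction. On the authors' values their log2 changes were -0.68 and -0.58. FOXA1, another factor that opens chromatin for the androgen receptor, rose by 0.24 (SE 0.07, adjusted p = 0.0159). This call ended without Abl siNT replicate 1 (0.19, adjusted p = 0.0689) or Abl siGATA2 replicate 2 (0.19, adjusted p = 0.0907), with a replicate block within each line or across groups (adjusted p = 0.0844 and 0.0721), and with no trend in the spread (adjusted p = 0.0613). HOXB13 (-0.02), TMPRSS2 (0.15) and FKBP5 (-0.09) were not called, with adjusted p values of 0.921, 0.307 and 0.580.

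Of 13 androgen receptor-repressed genes, 7 rose in Abl and 1 (DDC, -0.18) fell, with a median of 0.31 (adjusted p = 0.0179). The call was lost at adjusted p = 0.131 with an estimated correlation. CCN3, OPRK1 (1.18), PRKD1 (0.84) and UGT2B15 (0.58) were among the 7, and adjusted over the list alone 7 rose and 3 fell. Of 30 androgen receptor-induced genes, 7 rose, 3 fell and 20 were not called (median 0.05, adjusted p = 0.550), with the same counts adjusted over the list alone. Its members went both ways: KLK4, a prostate protease, fell by 1.23 (SE 0.11), CENPN by 0.79 and TRPM8 by 0.90, while RAB3B rose by 1.46 and STEAP2 by 0.54. KLK3, which encodes prostate-specific antigen, was not detected on any Abl array. Steroid synthesis and metabolism genes included 5 of 9 that rose, AKR1C3, UGT2B15, UGT2B17 (0.31), HSD17B4 (0.36) and HSD17B10 (0.25), with a median of 0.31. A replicate block within each line or across groups ended the calls of UGT2B17 (adjusted p = 0.137 and 0.0661) and HSD17B4 (adjusted p = 0.0935 and 0.0933), and HSD17B4 did not pass without eBayes moderation (adjusted p = 0.0569). The list had an adjusted p = 0.0112, adjusted p = 0.267 with an estimated correlation, and 6 higher adjusted over the list alone; probes of UGT2B genes may read close copies. Cholesterol synthesis and uptake genes rose in 8 of 21 cases, among them TM7SF2 (0.77), SC5D (0.67), HMGCS1 (0.53) and STARD4 (1.09). The list's median was 0.22 (adjusted p = 0.00246; adjusted p = 0.189 with an estimated correlation; 10 higher adjusted over the list alone). In the unfolded protein response list 16 of 28 genes rose and 4 fell, with a median of 0.30 (adjusted p = 0.00647; adjusted p = 0.206 with an estimated correlation; 16 higher and 6 lower adjusted over the list alone). DNAJB9, DDIT3 and DDIT4 rose by 0.91, 0.76 and 0.59, and PDIA4, ASNS, EDEM1 and CREB3L2 fell by 1.38, 0.47, 0.49 and 0.35.

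In MDVR, siGATA2 lowered KLK4, KLK2 and KLK3 and raised S100P by 3.64 log2 units (SE 0.17), although the GATA2 probe itself was not called. KLK4 fell by 1.91 (SE 0.11, adjusted p = 8.4e-10). KLK2 and KLK3 were detected on the 3 siNT arrays and on no siGATA2 array, so with the reported background correction KLK2 was at least 2.45-fold lower and KLK3 at least 1.31-fold lower. Their log2 changes were -0.38 and -0.16 on the authors' values. Of 61 G2/M genes 36 fell, 1 rose and 24 were not called, with a median of -0.38, and of 45 S phase genes 25 fell and 20 were not called (median -0.45). With an estimated correlation the G2/M call was lost (adjusted p = 0.131) and the S phase call was kept (adjusted p = 0.0462). In total 2638 genes changed, 1374 higher and 1264 lower, with 132 higher and 75 lower by at least 2-fold. The arrays did not overlap for 2556 of these, and for 36.3% of all genes, against 10% by chance. A test for a change beyond 1.5-fold called 163 genes.

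Further large rises in MDVR were KCNU1, a potassium channel gene (2.42, SE 0.12), SERPINA3, a protease inhibitor (2.28, SE 0.15), ARG2, an arginase (2.18, SE 0.10), and MATN2 (2.10, SE 0.08). MTMR9 rose by 1.93 (SE 0.09), ADGRV1 by 1.84 (SE 0.11) and TRIM2 at least 3.12-fold. UGT2B4 (2.07, SE 0.20) and GSTA5 (2.00, SE 0.17) rose as well, and both have close copies that their probes may read. Falls included SDCBP2 (-2.26, SE 0.20), AMACR, a racemase of branched fatty acids and a prostate cancer marker (-2.01, SE 0.12), COLCA1 (-2.01, SE 0.18), SPINT2 (-1.89, SE 0.07) and MIA3 (-1.74, SE 0.14). Over the alternatives the smallest rises were 1.37 for KCNU1, 1.42 for SERPINA3, 1.34 for ARG2 and 1.70 for MATN2. They were 1.16 for MTMR9, 0.88 for ADGRV1 and 0.64 for both UGT2B4 and GSTA5. The smallest falls were -0.76 for SDCBP2, -1.54 for AMACR, -0.74 for COLCA1, -1.81 for SPINT2 and -0.66 for MIA3. HEPACAM was at least 3.71-fold lower and ODAM at least 3.08-fold lower. The probe of KLKP1, a kallikrein pseudogene, was at least 2.54-fold lower, and it may read kallikrein copies. These bounds too depend on the processing. On the authors' values, which replaced several settings together, the log2 changes were 0.48 for TRIM2, -0.57 for HEPACAM, -0.52 for ODAM and -0.37 for KLKP1. MYC was not called (-0.22, SE 0.08, adjusted p = 0.0655), although it was on the average of its probes (-0.29, adjusted p = 0.00481) and without Abl siNT replicate 2 (adjusted p = 0.0435). Not called either were FOXA1 (0.11), HOXB13 (0.15), TMPRSS2 (-0.16) and FKBP5 (-0.09), with adjusted p values of 0.337, 0.298, 0.298 and 0.629; TMPRSS2 was called without MDVR siNT replicate 2 (-0.30, adjusted p = 0.0434).

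The cell cycle lists fell in MDVR by less than in Abl. In the G2/M list AURKB fell by 1.29 (SE 0.16), HJURP by 1.06, CDCA5 by 0.91 and PRC1 by 0.70, and TUBB4B was again the member that rose (0.30). The list had an adjusted p = 1.7e-13 (0.131 with an estimated correlation), and adjusted over the list alone 41 fell and 1 rose. UHRF1, which maintains DNA methylation at replication, fell by 1.74 (SE 0.12), and CDC45, NASP and FEN1 fell by 0.98, 0.95 and 0.65. The S phase list had an adjusted p = 5.6e-12, adjusted p = 0.0462 with an estimated correlation, and 27 lower adjusted over the list alone. Of 34 MYC and ribosome biogenesis genes 17 fell and 17 were not called (median -0.26, adjusted p = 2.4e-06; adjusted p = 0.0095 with an estimated correlation; 18 lower adjusted over the list alone). LYAR, RRS1, FBL and WDR12 fell by 0.98, 0.64, 0.55 and 0.49. Of 25 p53 targets 11 fell, 1 rose (RRM2B, 0.35) and 13 were not called (median -0.26, adjusted p = 0.00148; adjusted p = 0.0462 with an estimated correlation; 11 lower and 1 higher adjusted over the list alone). AEN (-0.82), PLK2 (-1.28) and XPC (-0.59) were among those that fell. CCNG1 fell by 0.34 on its brightest probe, but by the average of its 2 probes it changed by 0.0068.

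Of 9 genes linked to GATA factors 3 fell in MDVR, LMO4 (-0.49), FOXM1 (-0.76) and KLK3, with a median of -0.35 (adjusted p = 0.00472; adjusted p = 0.187 with an estimated correlation; 4 lower adjusted over the list alone). Of 28 type I interferon response genes 10 rose and 18 were not called, with a median of 0.17 (adjusted p = 0.00687; adjusted p = 0.0807 with an estimated correlation; 10 higher adjusted over the list alone). HERC5, IFI35, ISG15 and ISG20 rose by 0.68, 0.58, 0.55 and 0.54. The 6 metallothionein probes, which may read one another's RNA, included 4 that rose, MT1E (0.63), MT1G (0.42), MT1H (0.35) and MT2A (0.30). The median was 0.32 (adjusted p = 0.0147; adjusted p = 0.200 with an estimated correlation; 4 higher adjusted over the list alone), and without MDVR siGATA2 replicate 1 the list did not pass (adjusted p = 0.0555). The MT2A call (adjusted p = 0.0419) was lost without any 1 of 8 arrays, 4 of them from Abl (adjusted p = 0.0506 to 0.240), and with a replicate block within each line (adjusted p = 0.511), which also ended the call of the list (adjusted p = 0.0845). Fatty acid genes rose in 5 of 25 cases, THRSP (1.16), ACACB (0.77), ACSL1 (0.54), ACADVL (0.30) and ELOVL6 (0.29). The list's median was 0.14 (adjusted p = 0.0338; adjusted p = 0.189 with an estimated correlation; 5 higher adjusted over the list alone), and it did not pass without MDVR siGATA2 replicate 2 (adjusted p = 0.0651) or on the average of each gene's probes (adjusted p = 0.0749), where ACADVL was not called (adjusted p = 0.0767). Cholesterol genes rose in 7 of 21 cases, among them CYP51A1 (0.64), ACAT2 (0.50), HMGCS1 (0.47) and TM7SF2 (0.31), with a median of 0.12 (adjusted p = 0.0417; adjusted p = 0.275 with an estimated correlation; 8 higher adjusted over the list alone). That call was lost without MDVR siNT replicate 3, siGATA2 replicate 2 or siGATA2 replicate 3 (adjusted p = 0.0528, 0.0566 and 0.0853), or with detection required on all arrays of a group (adjusted p = 0.0580). TM7SF2 did not pass with a block within each line or across groups (adjusted p = 0.0857 and 0.0659).

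Hormone-linked genes in MDVR included 8 of 30 androgen receptor-induced genes that fell and 4 that rose, with 18 not called (median -0.08, adjusted p = 0.339; 9 lower and 4 higher adjusted over the list alone). KLF4 rose by 1.14, TARP by 1.43, ELL2 by 0.94 and STEAP2 by 0.43. Of 13 androgen receptor-repressed genes 8 rose, 2 fell and 3 were not called (median 0.33, adjusted p = 0.0728; 8 higher and 2 lower adjusted over the list alone). The list did pass with a replicate block within each line or across groups (adjusted p = 0.0134 and 0.0382), on the average of each gene's probes (0.0267) and without MDVR siGATA2 replicate 1 (0.0292). With an estimated correlation its camera adjusted p was 0.199. OPRK1 rose by 0.75 and DDC by 0.39, while BCHE fell by 0.82 and ST7 by 0.51.

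**Figure D2:**
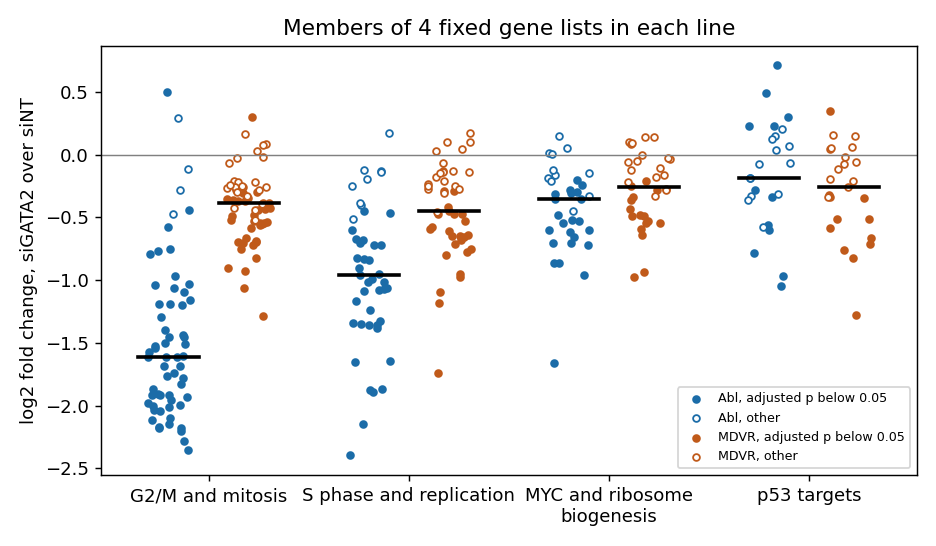
Log2 fold change (siGATA2 over siNT) of each measured member of 4 gene lists in Abl and MDVR; filled points have an adjusted p under 0.05, and bars mark the median. The median of the G2/M list was -1.61 in Abl and -0.38 in MDVR, and that of the MYC and ribosome biogenesis list was -0.36 and -0.26.

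The responses of both lines shared many genes. Of the genes called higher in Abl, 799 were also called higher in MDVR, against 208 expected from independent calls, and 810 were called lower in both, against 203 expected. S100P, CRYAB and VWF were among those that rose, and SPINT2, ODAM, KLK4 and AMACR among those that fell. Opposite calls were fewer than expected, with 26 genes higher in Abl and lower in MDVR (191 expected) and 18 the other way (221 expected). The contrasts share no arrays, but they share 1 estimate of spread per gene. The count expected from independent calls may therefore be too low. Across the 11933 genes the log2 changes correlated at Pearson r = 0.576 and Spearman rho = 0.528, where genes are not independent replicates. Without the genes of the 2 cell cycle lists r was 0.570, and 1549 of 11827 genes were called the same way. With a minimum fold of 1.5 in both lines, 72 genes were called the same way, against 1609 without it. With a block for replicate number within each line it was 1002.

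The response differed between the lines for 814 genes, 460 with a higher and 354 with a lower log2 change in MDVR than in Abl, and mitotic genes were the listed group with the smallest adjusted p. Of 61 G2/M genes 50 had a higher change in MDVR, that is a smaller fall, and 11 were not called. Their median difference was 1.18 (adjusted p = 3.6e-53; adjusted p = 0.0095 with an estimated correlation; 52 adjusted over the list alone). TOP2A differed by 1.91 (SE 0.15), PTTG1 by 1.80 (SE 0.13), CDC20 by 1.65 (SE 0.11) and HMMR by 1.61 (SE 0.13). CEP55 and DLGAP5 differed by 1.90 and 1.88, FOXM1 by 1.28 (SE 0.20) and MYC by 0.64 (SE 0.12). In the other direction, ID1 (-3.80, SE 0.27), ID3 (-2.70, SE 0.20) and AOC1 (-2.87, SE 0.22) rose more in Abl. SDCBP2 and MMP10, a matrix metalloproteinase, rose in Abl and fell in MDVR, and their changes differed by -3.04 (SE 0.28) and -2.51 (SE 0.28).

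Of 45 S phase genes 17 fell less in MDVR (median difference 0.53, adjusted p = 3.1e-14; adjusted p = 0.0355 with an estimated correlation; 21 adjusted over the list alone), among them RAD51AP1 (1.36), CDC45 (1.17) and GINS2 (1.09). PCNA differed by 1.01 on its brightest probe, but the average of its 3 probes was not called (0.47, adjusted p = 0.135). Among 6 metallothioneins MT1F (0.49), MT1G (0.41) and MT1X (0.49) were higher in MDVR relative to Abl (median 0.40, adjusted p = 0.00338; adjusted p = 0.167 with an estimated correlation; 5 adjusted over the list alone). The change of SERPINA3 was higher by 2.04 in MDVR, and that of BRDT by 2.40, although BRDT was detected on Abl siNT arrays only. The probes of ID1, AOC1, SERPINA3, KLK2, KLK3, RAB3B and TARP were also detected on no array of at least 1 group, so these differences are fitted values and not bounds. In the immediate early list FOS (-1.24), EGR1 (-0.82) and ATF3 (-0.56) were lower and MYC was higher, of 17 genes (median -0.18, adjusted p = 0.0216; adjusted p = 0.131 with an estimated correlation; 4 lower and 1 higher adjusted over the list alone). Leaving out any 1 of 8, 9 and 8 arrays ended the calls of MT1X, EGR1 and ATF3, with adjusted p up to 0.107, 0.108 and 0.105. A replicate block within each line ended the calls of MT1F (adjusted p = 0.118), MT1G (0.0998), MT1X (0.210), EGR1 (0.141) and ATF3 (0.207), and FOS did not pass without eBayes moderation (adjusted p = 0.0608). Among 34 MYC and ribosome biogenesis genes MYC and LYAR (0.68) were higher and SRM (-0.55) was lower (median 0.12, adjusted p = 0.0285; adjusted p = 0.131 with an estimated correlation; 4 higher and 1 lower adjusted over the list alone). That list did not pass without Abl siGATA2 replicate 2 or MDVR siGATA2 replicate 2 (adjusted p = 0.0541 and 0.0508). LYAR and SRM did not pass with a block within each line (adjusted p = 0.0607 and 0.0962), and MYC did not with a block across groups (adjusted p = 0.0513). Of 30 androgen receptor-induced genes 2 were higher, CENPN (0.81) and TARP (1.37), and 5 were lower, KLK2 (-1.74), RAB3B (-1.47), HERC3 (-0.90), SLC45A3 (-0.89) and KLK4 (-0.69). The median was -0.14 (adjusted p = 0.0403; adjusted p = 0.254 with an estimated correlation; 3 higher and 7 lower adjusted over the list alone). The call was lost when any of 6 arrays was left out: Abl siNT replicate 1 or 2 (adjusted p = 0.0577 and 0.0592), Abl siGATA2 replicate 2 or 3 (0.0541 and 0.0555), MDVR siNT replicate 4 (0.0862) or MDVR siGATA2 replicate 3 (0.0809). Of 13 androgen receptor-repressed genes 2 were higher and 3 lower (median -0.25, camera adjusted p = 0.0790, and 0.200 with an estimated correlation). That list passed under each of 5 other scalings (camera adjusted p = 0.0180 to 0.0498) and on the average of each gene's probes (0.0466). The KLK3 difference was not called (-0.81, SE 0.26, adjusted p = 0.0751), but its probe was detected on the MDVR siNT arrays only, so this value does not compare the falls in the 2 lines. It was called under 5 alternatives, with adjusted p down to 0.0293 (no trend in the spread). The changes did not differ detectably for FOXA1 (-0.13), HOXB13 (0.17), TMPRSS2 (-0.31) and FKBP5 (under 0.01 in size), with adjusted p values of 0.499, 0.535, 0.239 and 1. The count of 814 was 360 with a replicate block within each line, 523 without Abl siGATA2 replicate 4 and 67 with a minimum fold of 1.5.

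**Figure D3:**
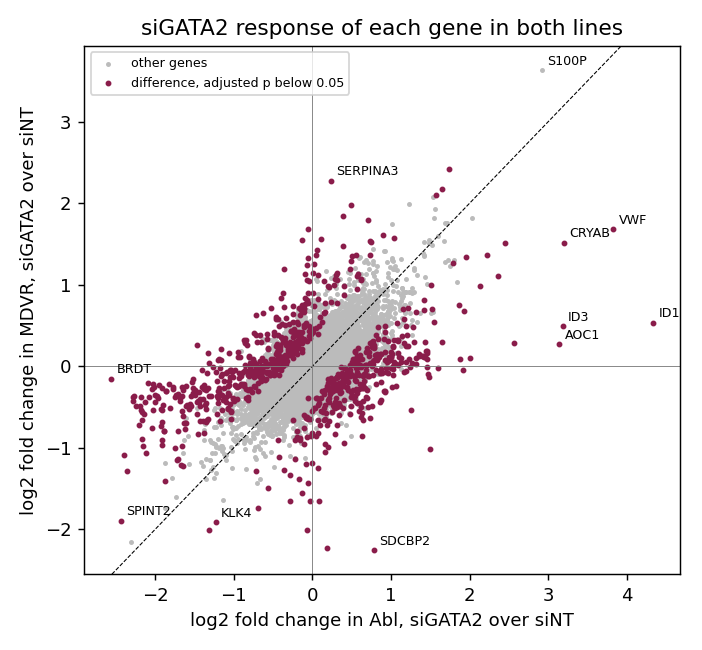
Log2 fold change (siGATA2 over siNT) of each of 11933 genes in Abl (horizontal axis) and MDVR (vertical axis); dark points are the 814 genes whose change differed between the lines, and the dashed line marks equal change. ID1, ID3 and AOC1 lie far to the right near 0 on the vertical axis, and S100P (2.92 in Abl, 3.64 in MDVR) is not among the dark points.

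Under siNT no list was called with an estimated correlation, so the counts below describe list members. MDVR had higher levels for 18 of 23 hypoxia response genes and lower levels for 1 (STC2, -0.47), with a median of 1.00 (adjusted p = 9.8e-07; adjusted p = 0.200 with an estimated correlation). PLOD2, a collagen lysyl hydroxylase, was higher by 5.49 (SE 0.21) and VEGFA, an angiogenic factor, by 2.88 (SE 0.11). Of 21 cholesterol genes 16 were lower in MDVR and 5 were not called, with a median of -0.87 (adjusted p = 3.9e-06; adjusted p = 0.0810 with an estimated correlation). INSIG1, a sensor of sterol levels, was lower by 2.19 log2 units (-2.19, SE 0.08). In total 6096 genes differed, 3048 higher and 3048 lower, and 156 were higher and 230 lower by at least 4-fold. The arrays did not overlap for 5856 of these and for 56.7% of all genes, against 10% by chance. With median scaling in place of quantile normalization 6080 differed, 3832 higher and 2248 lower, and the median of all genes was 0.13 above 0. A test for a difference beyond 1.5-fold called 1619 genes, and a replicate block within each line, which by construction compares the lines at their lowest-numbered replicates, left 3099.

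Large differences higher in MDVR were ATP1B1, a sodium pump subunit (6.60, SE 0.10), KIF1A (5.26, SE 0.12), PARP10 (5.10, SE 0.14), LIN7A (4.77, SE 0.11), MARCKS (4.68, SE 0.09), PPP3CA-DT (4.62, SE 0.11) and PXDN (4.53, SE 0.24). IRX4 and CLDN3, a tight junction protein, were at least 60.6-fold and 38.8-fold higher. Lower in MDVR were OR51E2, an olfactory receptor gene of prostate tissue (-8.73, SE 0.11), NDP (-6.14, SE 0.12), WDR72 (-6.13, SE 0.13) and TMSB4X, an actin-binding peptide (-5.83, SE 0.07). NTS, which encodes neurotensin, was at least 42.9-fold lower, HTATIP2 at least 43.3-fold and MALL at least 40.8-fold. PAGE1 and MAGEA4, genes of the cancer-testis class, were at least 124-fold and 81.3-fold lower, and NXF2 at least 41.9-fold; their probes may read close copies. These bounds depend on the processing. On the authors' values, which replaced several settings together, the log2 differences were 3.50 for IRX4, 2.92 for CLDN3, -4.42 for PAGE1, -3.87 for MAGEA4 and -2.96 for NXF2. They were -3.01 for NTS, -2.98 for HTATIP2, -2.92 for MALL and 0.20 for KLK3. Of the fixed genes, MYC was higher by 0.57 (SE 0.08), FOXA1 by 0.25 (SE 0.07) and KLK3 at least 1.28-fold. With a block within each line the FOXA1 difference was larger (0.37) but not called (adjusted p = 0.103). GATA2 was not called (0.19, adjusted p = 0.190), except without MDVR siNT replicate 2 (adjusted p = 0.0488). TMPRSS2 (0.04, adjusted p = 0.801) and FOXM1 (0.08, adjusted p = 0.663) were not called. HOXB13 was lower (-0.29, adjusted p = 0.0163), but not without Abl siNT replicate 3 (-0.23, adjusted p = 0.0831) or MDVR siNT replicate 2 (-0.20, adjusted p = 0.108), nor with median scaling (-0.17, adjusted p = 0.195) or a block within each line or across groups (adjusted p = 0.977 and 0.0571). FKBP5, a chaperone induced by androgens, was higher (0.30, adjusted p = 0.0345). It did not pass without Abl siNT replicate 1 or 2 (adjusted p = 0.151 and 0.109) or MDVR siNT replicate 3 or 4 (adjusted p = 0.102 and 0.0764). Nor did it with a block within each line (0.62, adjusted p = 0.0728) or across groups (0.32, adjusted p = 0.0769), although these estimates were larger. With no trend in the spread (adjusted p = 0.0605) or without eBayes moderation (adjusted p = 0.0803) it was not called either.

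Adjusted over the hypoxia list alone, 18 genes were higher and 1 was lower; BNIP3 and DDIT4 were higher by 1.37 and 1.14. Of 21 glycolysis genes 18 were higher and 2 were lower (HK1, -0.63, and ENO2, -0.66), with a median of 0.68 (adjusted p = 2.5e-05; adjusted p = 0.317 with an estimated correlation; 18 higher and 2 lower adjusted over the list alone). PFKFB4 (2.33), PFKP (1.76), SLC2A1, a glucose transporter (1.38), and ENO1 (0.86) were among the 18. The glycolysis and hypoxia lists overlap, and under siGATA2 their lowest log2 change was the same (-0.84 in Abl, -0.87 in MDVR). Their counts are therefore not independent. Adjusted over the cholesterol list alone, 16 genes were lower and 1 was higher; LSS, MVD and HMGCS1 differed by -1.75, -1.74 and -1.32. Oxidative phosphorylation genes were lower in 21 of 38 cases and higher in 1 (NDUFV1, 0.34), with COX6A1 at -0.65, COX5A at -0.64, COX6C at -0.53 and NDUFB5 at -0.51. The median was -0.23 (adjusted p = 0.00356; adjusted p = 0.217 with an estimated correlation; 21 lower and 1 higher adjusted over the list alone), and the call was lost with median scaling (adjusted p = 0.149) or a block within each line (adjusted p = 0.0553). Of 25 fatty acid genes 14 were lower, among them FASN (-0.88), ELOVL6 (-1.03) and ACSL4 (-3.04), and 5 were higher, THRSP (at least 7.21-fold; 1.09 log2 units on the authors' values), ACADM (0.81), ACADVL (0.74), DGAT2 (0.71) and GPAM (0.33). That list had a median of -0.34 (adjusted p = 0.0413; adjusted p = 0.198 with an estimated correlation; 15 lower and 5 higher adjusted over the list alone), and it did not pass with median scaling (adjusted p = 0.0558), a block within each line (adjusted p = 0.0788), detection on all arrays of a group (adjusted p = 0.0580) or only the arrays compared (adjusted p = 0.0542), or without MDVR siGATA2 replicate 2 (adjusted p = 0.0501). Of 45 ribosomal protein genes 15 were higher, among them RPL29 (1.20), RPL13 (1.19), RPS21 (1.05) and RPL22 (0.96), and 4 were lower (RPL5, RPL6, RPLP1 and RPS16, -0.24 to -0.16). The list had a median of 0.09 (adjusted p = 0.0381; adjusted p = 0.189 with an estimated correlation; 15 higher and 4 lower adjusted over the list alone), and it did not pass with cyclic loess (adjusted p = 0.0647) or only the arrays compared (adjusted p = 0.0542).

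Androgen receptor-induced genes differed between the lines in both directions, with 11 of 30 higher and 12 lower in MDVR (median -0.06, adjusted p = 0.626; 11 higher and 12 lower adjusted over the list alone). KLK4 was higher by 2.67 and PMEPA1 by 3.32, while ACP3, prostatic acid phosphatase, was at -5.28 and STEAP1 at -1.40. Of 13 androgen receptor-repressed genes 5 were higher and 6 lower, with DDC at -3.19, OPRK1 at -2.88, UGT2B17 at -2.46 and UGT2B15 at -2.19. That list's median was 0.28 and its mean -0.58, which differ in sign (adjusted p = 0.519).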

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

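The tests that weigh the 3 patterns below were chosen after the results were seen; the counts over other splits of the arrays were planned.

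A test of the difference between the 2 lines passed its threshold for 814 genes, which brought this result here, as it did the lists and genes that follow, all given as the MDVR effect minus the Abl effect. Of 100 splits that regrouped the arrays within each line, 5 gave as many genes, the real one included. The highest of the others gave 4557, several times the real count. That split and the 3 others above the real count (1483 to 1629 genes) keep the Abl arrays as they are and exchange 2 or 3 MDVR siNT arrays with siGATA2 arrays. This turns a difference of effects into a sum of effects. These splits hold real siRNA effects, so the count cannot decide whether chance accounts for the 814 genes. For the 6 lists called in the difference, 43 of the 100 splits gave as many, up to 12. These splits too keep part of the siRNA effects, so they cannot decide whether chance accounts for the number of lists. The counts of genes changed in Abl (3725, highest other split 1), in MDVR (2638, highest other 0) and between the lines under siNT (6096, highest other 0) come from designs with 10 splits, which are too few for a share under 0.05. For the lists called in Abl (7, highest other 7) and in MDVR (9, highest other 9), 3 of the 10 splits gave as many in each line. These include the real split. Each other split puts 2 arrays of 1 label with 1 of the other, so part of the siGATA2 effect stays in it. The number of lists therefore cannot decide about chance. Under siNT no other split gave as many lists (6, highest other 5), again with too few splits for a share under 0.05. For the genes called the same way in both lines, 1 of 100 splits, the real one, gave 1609 and the highest other gave 44. The 44 are the genes called in opposite directions (26 and 18), which count as shared once all MDVR labels are exchanged. Other regroupings of the arrays within 1 line called 0 or 1 genes there, which leaves almost nothing to share, so this count adds nothing to the counts per line.

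G2/M and mitosis genes fell more in Abl than in MDVR, with a median difference of 1.18. The background correction or normalization is argued against as the source of the difference, since at least 43 of the 61 members had a called difference under each of 5 other scalings. Its size does depend on the background correction: the medians in Abl and MDVR were -1.61 and -0.38 in the reported fit, -0.98 and -0.28 with no correction, and -0.74 and -0.23 on the authors' values. A smaller response of all genes in MDVR may contribute. Genes called higher in Abl and matched in size kept 47.1% of their Abl change in MDVR (95% bootstrap interval 27.3% to 72.1%). The G2/M genes called lower in Abl kept 23.8% (19.7% to 30.03%), and these intervals overlap. They resample genes, which are not independent replicates, and leave out the spread between arrays, so they cannot decide the question. The matching set no condition on detection. A weaker loss of GATA2 mRNA in MDVR cannot be told apart either, because the GATA2 difference has an adjusted p = 0.458 and an interval from -0.11 to 0.58. The lines, with their serum and enzalutamide, stay open as an untested biological explanation.

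The GATA2 probe was not called lower in MDVR while 2638 genes changed there. Wrong siRNA labels are argued against. A score was made from 3567 genes called in a separate fit of the Abl arrays alone, with GATA2 left out. On it the lowest MDVR siGATA2 array lies 0.30 above the highest MDVR siNT array, and no group spans more than 0.021. A signal near background is argued against as well, since the probe lies at least 3.71 log2 units above the lowest detected probe on each MDVR array. A probe that reads RNA which the siRNA does not remove may be involved and cannot be told apart, because only 1 named GATA2 probe was measured. Effects of the single siRNA on other RNAs and changes in GATA2 protein were not tested and stay open.

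KLK2 and KLK3 fell in MDVR and were not called in Abl. Both were detected on 0 of the 3 Abl siNT arrays, so a fall in Abl had no signal from which to start, and this may account for the pattern. For KLK4, detected on all 12 arrays, a response limited to MDVR is argued against, since it changed by -1.23 in Abl. For KLK2 and KLK3 such a response stays open. The 6 KLK genes differed between the lines as a set (median -0.57, adjusted p = 0.0278, and 0.571 with an estimated correlation), which includes probes with no signal in Abl. KLK2 differed between the lines by -1.74 and KLK4 by -0.69, and for KLK3 the difference was not called, although 5 alternatives called it, on a probe detected in MDVR under siNT only.

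Of the lists, the median difference was 1.18 for G2/M genes, 0.53 for S phase genes, 0.40 for metallothioneins and 0.12 for MYC and ribosome biogenesis genes. It was -0.18 for immediate early genes and -0.14 for androgen receptor-induced genes.

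Among mitotic and replication genes, the difference was 1.91 for TOP2A, 1.90 for CEP55, 1.88 for DLGAP5, 1.80 for PTTG1 and 1.85 for the near copy PTTG3P. It was 1.76 for DEPDC1, 1.65 for CDC20, 1.61 for HMMR, 1.56 for NEK2, 1.48 for CDCA3 and 1.07 for AURKB. HJURP, CDCA5, PRC1 and CENPN differed by 1.05, 1.01, 0.91 and 0.81. The replication genes RAD51AP1, MCM10, CDC45, GINS2, PCNA and FEN1 differed by 1.36, 1.30, 1.17, 1.09, 1.01 and 0.67. FOXM1 and MYC differed by 1.28 and 0.64, LYAR by 0.68 and SRM by -0.55.

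Genes that rose more in Abl included ID1 (-3.80), ID3 (-2.70), ID2 (-0.94), AOC1 (-2.87), CCN3 (-2.29), VWF (-2.15), CRYAB (-1.68), AKR1C3 (-1.25), RAB18 (-0.85) and PRKD1 (-0.73). RAB3B (-1.47) and STARD4 (-0.93) did so as well, on probes that were not detected in MDVR. SDCBP2 differed by -3.04 and MMP10 by -2.51, and both moved in opposite directions in the lines. Genes that fell in MDVR, with a lower log2 change there than in Abl, included HEPACAM (-2.42), COLCA1 (-1.94), KLKP1 (-1.37) and MIA3 (-1.04). AMACR (-0.70), PLK2 (-0.91) and ST7 (-0.54) did so too, and not all of these genes fell in Abl. The ST7 difference was not called with a replicate block across groups (-0.56, adjusted p = 0.0539). CCNG1 differed by -0.57 on its brightest probe, but its change in MDVR was 0.0068 on the average of its probes. The immediate early genes FOS, EGR1 and ATF3 differed by -1.24, -0.82 and -0.56, and the stress genes DNAJB9, DDIT3, DDIT4 and PDIA4 by -0.58, -0.53, -0.36 and 0.57. TM7SF2, a sterol reductase gene, differed by -0.46.

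In the other direction, SERPINA3 differed by 2.04, TRIM2 by 1.49, ADGRV1 by 1.45, TARP by 1.37, KCNU1 by 0.68, ARG2 by 0.53, MATN2 by 0.53 and ACSL1 by 0.42. BRDT differed by 2.40 on a probe detected on Abl siNT arrays only. SPINT2 and DDC differed by 0.55 and 0.57, and MT1F, MT1X and MT1G by 0.49, 0.49 and 0.41. The values of ID1, AOC1, CCN3, RAB3B, STARD4, BRDT, SERPINA3, TARP, TRIM2, HEPACAM, KLK2 and KLKP1 involve a group with the probe on no array above background, so they are fitted values and not bounds.

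Probes without a single gene symbol, which the gene counts leave out, also responded to siGATA2: of 6672 such probes, 751 were called in Abl and 563 in MDVR (11.3% and 8.44%, against 26.6% and 18.4% of kept probes with a symbol).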

How the results depend on the processing

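The replicate block across all groups was chosen after seeing the data; the other alternatives were planned. Across 224 results for named genes, 6240 of 6449 values under alternatives kept their direction and side of the threshold, 176 lost the call, 12 gained one and 21 changed direction, and 132 of the 224 results never changed. Part of this agreement is built in. Testing every probe on its own reads the same probe, and leaving out an array of the other line keeps the log2 change within a line. Many of these genes were also picked for large or clearly called changes in the reported fit. Sizes moved more than calls. Log2 changes were smaller with weaker background correction and on the authors' values, which replaced several settings together. Of 203 called changes of named genes, 95 were smaller by over 1.5 times on the authors' values (at the median 69.0% of the reported change), 74 with no background correction (78.8%) and 32 with normexp at offset 50 (88.2%). FOXM1 in Abl ran from -2.14 to -0.71 over the alternatives, AURKB from -2.43 to -0.77, VWF from 1.52 to 3.96 and RAB3B from 0.35 to 1.54. Of 945 values for the lists 885 were kept, 45 lost and 15 gained the call. A minimum fold of 1.5, a stricter question by construction, called 364 genes in Abl, 163 in MDVR, 67 in the difference and 1619 under siNT, with 72 shared, and ended 80 calls of named genes. A block for replicate number within each line gave 360 for the difference, 3099 under siNT and 1002 shared; the block across all groups gave 273 for the difference, 1053 shared and 5408 under siNT. The block within each line makes the contrast under siNT one between the lowest-numbered replicates of the lines. It also rests the change within a line on replicates 2 and 3 alone, the numbers present under both siRNAs. Both blocks leave fewer residual degrees of freedom than the reported fit. How far this accounts for the other falls was not tested. The numbers shared within a line (2 and 3) carried little else in common (r of residuals 0.0040 to 0.112). With an estimated correlation 3, 3, 2 and 0 lists were called (Abl, MDVR, difference, siNT), and with fry, which does not compare a list with other genes, 20, 22, 14 and 25. Leaving out 1 array gave 3060 to 3791 genes in Abl, 2096 to 2739 in MDVR, 523 to 750 for the difference (523 without Abl siGATA2 replicate 4), 5536 to 6126 under siNT and 1350 to 1548 shared, with 7 to 9, 7 to 13, 4 to 9 and 5 to 8 lists. Direction changed for the genes that follow. Apart from CCNG1 in MDVR and HOXB13 under siNT, their reported changes were small and not called. The cause of the changes in direction was not tested. HOXB13 in Abl became 0.0046 with cyclic loess and ran from -0.063 to 0.048 over arrays left out, and FKBP5 in Abl from -0.17 to 0.028. The FKBP5 difference became 0.031 with median scaling, 0.00079 with cyclic loess and 0.025 with array weights, and ran from -0.12 to 0.083. CCNG1 in MDVR was 0.0068 on the average of its probes. Under siNT, HOXB13 was 0.011 with the block within each line. TMPRSS2 was -0.0031 with cyclic loess and -0.019 with the block across groups, and ran from -0.050 to 0.17, and FOXM1 from -0.028 to 0.17. Over the alternatives the adjusted p ran from 0.00646 to 1 for GATA2 in Abl, 0.106 to 1 for GATA2 in MDVR, 0.00347 to 1 for FOXA1 in Abl and, under siNT, 0.00453 to 1 for HOXB13 and 0.00342 to 1 for FKBP5, where 1 came from the minimum fold, and from 5.7e-07 to 0.135 for the PCNA difference. A chip block was not run, as no chip is named in the labels used here, and fitting only the arrays compared does not apply to the difference. Signal over background limits probes such as KLK3, whose changes are given as bounds.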

Other observations

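Genes that share a symbol stem were tested as an exploratory set of 397 stems (1588 tests over the 4 contrasts, adjusted together), chosen after the data were seen. None held with an estimated correlation (adjusted p = 0.532 or above). In Abl all 6 measured HOXC genes, which pattern the body axis, rose (median 1.10, adjusted p = 0.00171), among them HOXC4 (1.54), HOXC13 (1.14) and HOXC6 (0.56). These 3 rose in MDVR as well, by 0.67, 0.59 and 0.54, and the other 3 were not called there. The stem differed between the lines (median -0.81, adjusted p = 0.00964), with 2 of the 6 genes lower in MDVR relative to Abl, HOXC12 (-1.25) and HOXC8 (-1.04), whose probes were detected on no MDVR array. Of 13 HLA genes, which present antigens and share much sequence, 7 rose in Abl (median 0.45, adjusted p = 0.0278), with HLA-C at 1.19 and HLA-B at 0.94. Of 10 UGT genes 6 rose in Abl (median 0.42, adjusted p = 0.0272), and of 13 HSD genes 8 rose (median 0.37, adjusted p = 0.00549). Among other stems in Abl, 10 of 11 LSM genes fell (median -0.48, adjusted p = 0.00211), as did 12 of 21 NUP genes (median -0.30, adjusted p = 0.00027) and 20 of 50 MRPL genes, with 2 higher (median -0.16, adjusted p = 0.00781). In MDVR 5 of 6 beta-tubulin (TUBB) genes rose (median 0.99, adjusted p = 0.00781), with TUBB2A at 1.32 and TUBB3 at 1.10, and 4 of 6 kallikrein (KLK) genes fell (median -0.67, adjusted p = 0.0147). The KLK stem also differed between the lines (median -0.57, adjusted p = 0.0278), with 2 of 6 lower, KLK2 and KLK4, of which KLK2 was not detected in Abl. Under siNT all 12 GAGE probes were lower in MDVR (median -2.27, adjusted p = 9.8e-14); these genes are near copies, so the 12 values are not independent.

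Lists of other cell types did not pass in the siGATA2 contrasts. Of 5 blood and endothelial markers 2 rose in Abl, VWF and CD68 (0.53), and the list had an adjusted p = 0.174. In MDVR VWF rose by 1.68 and CD2 fell by 0.60 (adjusted p = 0.412). Of 3 fibroblast and smooth muscle markers TAGLN rose in Abl (1.00) and ACTA2 fell in MDVR (-0.73), with adjusted p = 0.145 and 0.966 for the list. JAG2 was the basal marker of 4 that fell in Abl (-0.56, list adjusted p = 0.586) and in MDVR (-0.58, list adjusted p = 0.256). Luminal markers went both ways, with 7 of 22 higher and 2 lower in Abl (adjusted p = 0.229), CDH1, or E-cadherin, among them (1.21), and 3 higher and 4 lower in MDVR (adjusted p = 0.865). Of 11 neuroendocrine markers 1 rose and 3 fell in Abl (adjusted p = 0.485), with PEG10 at -1.17, and under siNT 2 were higher and 7 lower in MDVR (adjusted p = 0.0790). Of 12 mesenchymal genes 2 rose and 2 fell in Abl (adjusted p = 0.725).

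Regulatory lists that missed the threshold held some called members. Of 9 genes linked to GATA factors 4 fell in Abl, GATA2, FOXM1, MYC and LMO4 (-0.42), with the list at adjusted p = 0.0900. Of 25 p53 targets 5 rose and 7 fell in Abl (adjusted p = 0.389), with GDF15 at 0.71 and SPATA18 at -1.05. TSC22D3 and SGK1, targets of the glucocorticoid receptor, rose in both lines, SGK1 by 1.03 in Abl and 0.93 in MDVR, where 5 and 6 of 12 list members rose (adjusted p = 0.204 and 0.0851). The chemokine genes CCL20 and CCL2 fell in Abl by 1.34 and 1.16, and 5 of 13 NF-kB genes fell there (adjusted p = 0.119). RNF43, a Wnt target, changed by -1.64 in Abl and by -0.90 in MDVR, with the list at adjusted p = 0.158 and 0.0547. Of 25 apoptosis regulators 4 rose and 3 fell in Abl (adjusted p = 0.737), with BIRC5, or survivin, at -2.04, and 5 rose and 3 fell in MDVR (adjusted p = 0.834), with PMAIP1 at 1.14. Of 17 immediate early genes 7 rose and 2 fell in Abl (adjusted p = 0.144). The heat shock list was not called in Abl (adjusted p = 0.820) or in MDVR (adjusted p = 0.158). The androgen receptor coregulator list was not called in either line (adjusted p = 0.594 and 0.174); GRHL2 fell by 0.41 and 0.33 and KDM1A by 0.41 and 0.35. The members named here were chosen after their values were seen.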
